A study of Homo sapiens with 2 samples.

How the data were processed

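RNA from HMEC-1, a line of human dermal microvascular endothelial cells immortalised with SV40, was compared on 2 two-colour expression arrays. Per the labels, confluent cells of passage 8 received 100 ng/ml tumour necrosis factor alpha (TNF-α) or were left untreated, and were harvested after 4 h or 24 h. For each of the 4 conditions, 3 cultures were grown and treated independently and their RNA was pooled before labelling. Each array therefore set 1 pool of treated cells, labelled with Cy5, against 1 pool of untreated cells of the same time point, labelled with Cy3. Each labelling started from 1 µg of total RNA with an integrity number of at least 9.9, per the labels' protocols. The dyes were not exchanged on any array used here. Both arrays lay on the same slide and were read in the same scan, so slide and scan did not differ between the time points.

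The deposited scanner files hold the brightness (intensity) of each spot and of its surroundings in both dyes, together with processed intensities and quality flags. They were written by Agilent Feature Extraction 9.5.1.1 with the protocol GE2-v5_95_Feb07, per the file headers. The software subtracted background, corrected gradients across the array and normalised the dyes by a linear and a lowess step, per the file headers, and the log10 ratio of Cy5 over Cy3 and its error come from those processed signals. The deposited value table holds the same log10 ratio rounded to 4 decimals, with the same spot numbers and the same direction, and its median was 0.0 on both arrays. In that ratio a spot is set to 0 when neither channel is above background.

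The log2 ratios given here were computed from the scanned signals with limma 3.58.1 in R 4.3.3. The mean signal of each spot was corrected for the median local background by the normexp method with an offset of 50, fitted on all 45015 spots. A loess curve with a span of 0.3 was then fitted within each array, with the 1639 control spots at weight 0. Control spots and spots with an outlier flag, 156 on the 4 h array and 170 on the 24 h array, were left out afterwards. Spots of the same probe were averaged on the log2 scale, which left 41000 probes. All ratios are TNF-α over control and are relative to the typical gene of the same array. The offset of 50 pulls ratios of dim spots toward 0, so that folds of dim genes are understated.

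Gene symbols were updated through the RefSeq accessions, symbols and older symbols of the GRCh38.p14 annotation, which was used for names only. This named 23429 probes by accession, 2320 by current symbol and 1043 by an older symbol, while 14208 kept the name in the file. Of 30990 gene names, 17518 had a RefSeq symbol. Each name was counted as a gene, so a gene whose probes kept different names can be counted more than once. The genome build of the probe coordinates in the files is not given in the sources used here, so no coordinates are printed. One probe stood for each gene: the one with most of its 4 channel values well above background and unsaturated, with ties settled by mean signal. A gene was measured at a time point where this probe was well above background in both channels by the scanner software's flag. Where 1 channel was not, and no other probe of the gene was above background in it, the gene was given only a lower bound. The bound sets the bright channel against the higher of the dim channel's own signal and the lowest signal called well above background, after loess and Aquantile normalisation, and it is open to dye effects. Where the dim channel's own signal was the higher, the bound is the ratio itself. It then carries the error of a dim spot and is not a guaranteed minimum.

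With 1 array per time point there was no spread between replicates and no test. Genes were called by a fixed rule of size, a log2 ratio of at least 1 or at most -1, which is 2-fold. The error printed after a log2 ratio is the scanner software's estimate for its own processed ratio of that spot. It was not computed for the ratio it follows. For dim genes the processed ratio can differ by more than this error, as for GBP2 at 4 h (1.91 here, 3.09 processed, error 0.36). The error covers the reading of the spot and the dye normalisation, not the difference between cultures. An effect of the dye on a probe cannot be told apart from an effect of TNF-α within an array. It cancels in the difference between the time points if it is the same on both arrays. Gene lists were described by the number of measured members past the size rule and by the percentile of their median among 10000 random lists of the same size, matched on mean signal in 20 bins.

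The design, the alternatives, the 24 gene lists with 609 entries and the rule for named genes were fixed before the data were examined. The rule took, per time point, the 12 largest positive and 8 largest negative log2 ratios among genes with a symbol that were measured and unsaturated, and the 5 largest lower bounds in each direction. It also took the 8 largest differences between time points in each direction, 8 fixed genes (SELE, VCAM1, ICAM1, CCL2, CXCL8, IL6, NFKBIA and TNFAIP3) and up to 4 members of each list. The alternatives were no background correction, an offset of 16, centring on the median in place of loess, the software's processed signals, the deposited table, the mean over a gene's probes, other rules for dim and saturated spots, other size thresholds, scaling between arrays and unmatched random lists. A further 3 alternatives were added after the data were seen: centring on the spike-in controls, a loess span of 0.02, and leaving out genes with a mean log2 signal of 16 or more.

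The procedure was tested on simulated arrays of 45015 spots in which 50 spots per array and true ratio had known values. A true log2 ratio of 1 came back with a median of 0.82 on the simulated 4 h array and 0.86 on the simulated 24 h array, and a true ratio of 2 with medians of 1.70 and 1.81. For true ratios of -1 the medians were -0.80 and -0.88, and for -2 they were -1.51 and -1.70. None of the 30869 and 28722 unchanged simulated spots reached 2-fold. The simulated arrays held random noise and a smooth dye curve, but no dye effect of single probes. That count therefore cannot show how often such an effect, or a trend left by the loess, gives a call. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.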

Results

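The response of HMEC-1 microvascular endothelial cells to 100 ng/ml TNF-α was measured after 4 h and after 24 h, with an untreated control at each time. Each time point was 1 array of pooled RNA from 3 cultures per condition, so no value below has a replicate error. At 4 h, 21842 genes were well above background in both channels, and at 24 h this held for 20268. Median raw signals were 320.9 in the TNF-α channel and 166.9 in the control channel at 4 h, and 334.7 and 175.4 at 24 h, over local backgrounds of 43.0 to 54.5. Among probes spotted 10 times, the median SD of the log2 ratio between spots was 0.048 at 4 h (231 probes) and 0.039 at 24 h (221 probes). The software's error had a median of 0.21 on the log2 scale on both arrays.

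The first comparison asked which transcripts differed after 4 h of TNF-α. Several inflammatory and NF-κB genes were far higher in treated cells, and next to nothing was lower by 2-fold. Most measured members of the NF-κB, chemokine, cytokine and adhesion lists stayed short of 2-fold. CXCL8, a chemoattractant of neutrophils, was 13.6-fold higher (log2 ratio 3.77 ± 0.41). It was followed by UBD, a ubiquitin-like modifier, at 11.7-fold (3.54 ± 0.46), and BIRC3, an inhibitor of apoptosis, at 10.6-fold (3.41 ± 0.38). TNFAIP6, which encodes a hyaluronan-binding protein, was 9.91-fold higher (3.31 ± 0.38), the chemokine CCL20 8.45-fold (3.08 ± 0.41), TNFAIP2 8.16-fold (3.03 ± 0.35) and the pentraxin PTX3 7.26-fold (2.86 ± 0.34). This order depends on the processing: with the software's processed signals UBD lay above CXCL8, at log2 ratios of 4.32 and 3.80. In all, 131 measured genes were at least 2-fold higher and 1 was at least 2-fold lower in the values used here. Of the called genes 43 had other probes, and in 16 of these all probes passed 2-fold the same way. With the lower bounds given next, 112 of the higher calls had a RefSeq symbol. Some of the rest lay close to probes of genes already counted, SOD2, INHBA and SERPINB2 among them, by the coordinates in the scanner output. A further 5 genes passed 2-fold as lower bounds because their control channel was not well above background: CGNL1 (4.36-fold), ELOVL7 (3.19-fold), SGPP2 (2.23-fold), ERAP2 (2.15-fold) and TNIP3 (2.12-fold). Each of these bounds equals the probe's own ratio. Those of SGPP2, ERAP2 and TNIP3 exceeded 2-fold by less than the software's error of the spot. Each bound concerns only the probe used. The other probes of ELOVL7, SGPP2 and ERAP2 had log2 ratios of 0.46, 0.42 and 0.39 at 4 h, short of 2-fold. No lower bound reached 2-fold in the other direction.

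Of the list of NF-κB subunits and feedback regulators, 10 of 24 measured members were at least 2-fold higher at 4 h, and the list median of 0.53 was at percentile 100.0 of the random lists. The largest ratios belonged to genes of inhibitors of the pathway, a subunit and an adaptor. NFKBIE, which encodes an inhibitor, was 6.23-fold higher (2.64 ± 0.32), TNFAIP3, which encodes the deubiquitinase A20, 6.16-fold (2.62 ± 0.32), the subunit gene RELB 6.13-fold (2.62 ± 0.32) and the adaptor gene TRAF1 4.87-fold (2.28 ± 0.32). NFKBIA, which encodes IκBα, was 4.79-fold higher (2.26 ± 0.29).

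Secreted inflammatory mediators made up the next group. Among chemokines, 6 of 14 measured genes were at least 2-fold higher (list median 0.15, percentile 99.85). Besides CXCL8 and CCL20 these were CXCL1 at 6.44-fold (2.69 ± 0.33), CXCL2 at 6.41-fold (2.68 ± 0.32), CCL2, a chemoattractant of monocytes, at 4.64-fold (2.22 ± 0.36), and CXCL3 at 3.74-fold (1.90 ± 0.27). Another 10 chemokine genes were not well above background in either channel. Among cytokines and colony-stimulating factors, 8 of 21 were at least 2-fold higher (median 0.31, percentile 100.0), with IL6 at 4.79-fold (2.26 ± 0.32), IL1A at 3.98-fold (1.99 ± 0.29), IL1B at 3.84-fold (1.94 ± 0.27) and CSF2 at 2.94-fold (1.56 ± 0.32).

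Adhesion molecules for leukocytes gave a narrower picture. ICAM1, the ligand of leukocyte integrins, was 6.75-fold higher (2.76 ± 0.33) and was the only member of 13 measured ones past 2-fold. CD58, ICAM2 and CD47 had log2 ratios of 0.73, 0.64 and 0.50, and the list median of 0.23 was at percentile 99.97. SELE (E-selectin) and VCAM1, the other classical TNF-α targets in endothelium, were not well above background in either channel at 4 h, and the same held for PECAM1, SELP, CD34, JAM2 and JAM3, named after their signals were seen. Each of SELE and VCAM1 had 1 probe on the array.

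Survival genes were higher as a group, with 4 of 18 past 2-fold and a median of 0.32 (percentile 100.0). After BIRC3 and TRAF1, these were TNFAIP8 at 3.29-fold (1.72 ± 0.26) and SOD2, the mitochondrial superoxide dismutase, at 3.10-fold (1.63 ± 0.26), or 1.29 as the mean over its probes. Of 22 pro-apoptotic genes and death receptors none reached 2-fold (median 0.12, percentile 99.90). Their largest log2 ratios were 0.94 for FAS and 0.87 for TNFRSF10B. No immediate-early or AP-1 gene of 21 reached 2-fold (median 0.27, percentile 100.0). Values there were 0.74 for JUNB, 0.71 for ATF3, 0.58 for MAFF and -0.58 for MYC.

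Of 44 measured interferon-stimulated genes, 6 were at least 2-fold higher at 4 h, with a list median of 0.11 (percentile 99.98). The guanylate-binding proteins GBP2, GBP3 and GBP1 were at 3.75-fold (1.91 ± 0.36), 3.46-fold (1.79 ± 0.27) and 3.35-fold (1.74 ± 0.26). RIGI, a sensor of viral RNA, was at 4.18-fold (2.06 ± 0.29). Among genes of MHC class I presentation, the peptide transporter TAP1 was 3.01-fold higher (1.59 ± 0.25), the only measured member of 20 past 2-fold (median 0.15, percentile 99.93).

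Endothelial identity, junction and coagulation lists had medians near 0 at 4 h, while growth factor and matrix lists lay above most random lists. None of 26 measured endothelial identity genes passed 2-fold (median 0.04, percentile 74.93), GATA2 being the furthest from 0 at -0.56. Another 11 of that list, PECAM1 and, named after their signals were seen, TIE1 and FLT1 among them, were not well above background in either channel. CLDN1, a tight-junction claudin, was 3.53-fold higher (1.82 ± 0.27), the only such gene of 18 in the junction list (median 0.04). In the coagulation list 2 of 19 passed (median 0.05): SERPINB2, an inhibitor of plasminogen activators, at 3.04-fold (1.60 ± 0.31), and ANXA2 at 2.02-fold, discussed with the brightest genes below. A brighter probe without a symbol, close to that of SERPINB2 by the coordinates in the scanner output, was 5.40-fold higher (2.43 ± 0.31). It was described here after its value was seen and counted as a separate gene. Of 31 growth factors and vascular mediators, 3 passed (median 0.10, percentile 99.42): INHBA, a subunit of activin, at 4.49-fold (2.17 ± 0.29), EFNA1 at 3.56-fold (1.83 ± 0.27) and EREG at 2.29-fold (1.19 ± 0.23). No matrix gene of 35 passed (median 0.08, percentile 98.66).

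In the list of tryptophan, arginine and pterin metabolism, GCH1, the first enzyme of tetrahydrobiopterin synthesis, was 2.95-fold higher (1.56 ± 0.32) and the amino-acid transporter gene SLC7A2 2.21-fold (1.15 ± 0.24), out of 12 measured (median 0.12). SOD2 alone of 27 oxidative and metal stress genes passed 2-fold (median 0.21). Cell cycle genes had a median of -0.11 (percentile 0.14), with 1 of 42 past the rule, the cell cycle inhibitor CDKN2B at 2.21-fold (1.14 ± 0.23), whose mean over probes of 0.99 was short of 2-fold. That negative median turned to 0.25 when arrays were centred on their median without loess. Cholesterol synthesis (median -0.06, 28 genes, but 0.24 under median centring), the unfolded protein response (-0.01, 19 genes, but 0.37), glycolysis and hypoxia (0.08, 24 genes) and reference genes (0.11, 20 genes) had no member past 2-fold. Of marker lists, leukocytes (median 0.06, 13 genes) and fibroblasts and mural cells (0.07, 15 genes) had none either, and epithelial cells (0.01, 12 genes) had 1, the transcription factor gene ELF3 at 2.97-fold (1.57 ± 0.35).

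Few transcripts were lower by 2-fold at 4 h in the values used here, 1 gene against 13 with the software's processed signals. The single gene past 2-fold was a predicted transcript without a symbol, with a log2 ratio of -1.20 ± 0.23, described here after its value was seen. The named genes furthest below 0 were the cannabinoid receptor gene CNR1 (-0.95 ± 0.22), IER5L (-0.82), PDK4 (-0.82), RIN1 (-0.77), BMP4 (-0.76), FZD2 (-0.75), KLF15 (-0.75) and CCN2 (-0.72), each less than 2-fold. With the processed signals KLF15 (-1.76), BMP4 (-1.58) and CNR1 (-1.02) passed 2-fold. In the values used here the other probe of KLF15 was at -0.02 and that of CNR1 at -0.35. Bounds for genes not well above background in the TNF-α channel were 1.28-fold lower for HOXA9, 1.27-fold for SLITRK6, 1.23-fold for TMEM144 and 1.22-fold for LIPH and GCNT3. On the log2 scale each was smaller than the software's error of the spot.

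All of these values are relative to the typical gene of the array. The scanner software fits a line of observed on expected log ratio to the spike-in controls, with slopes of 0.859 at 4 h and 0.866 at 24 h. Carried to the values used here, its intercept in log2 was -0.68 at 4 h and -0.54 at 24 h. This is the offset of a control with an expected ratio of 0. Centred on it, 1269 and 761 measured genes would be at least 2-fold higher and 0 lower. The amounts of spike-in mix added to each channel are not given in the sources used here, so unequal amounts are not excluded as the source of that offset. That centring adds the same amount to every ratio of an array, so it moves list medians from below 0 to above 0 and leaves their places among random lists. The brightest genes also lay above the rest: 547 genes with a mean log2 signal of 16 or more had a median log2 ratio of 0.27 at 4 h and 0.33 at 24 h, and they held 13 and 23 of the higher calls. None of these bright genes passed 2-fold with a loess span of 0.02, while 121 and 102 of the higher calls did. That span brought the median of the bright genes to 0.004 and 0.01. It would do the same to a rise with TNF-α that these genes shared, so it does not show the cause.

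**Figure D1:**
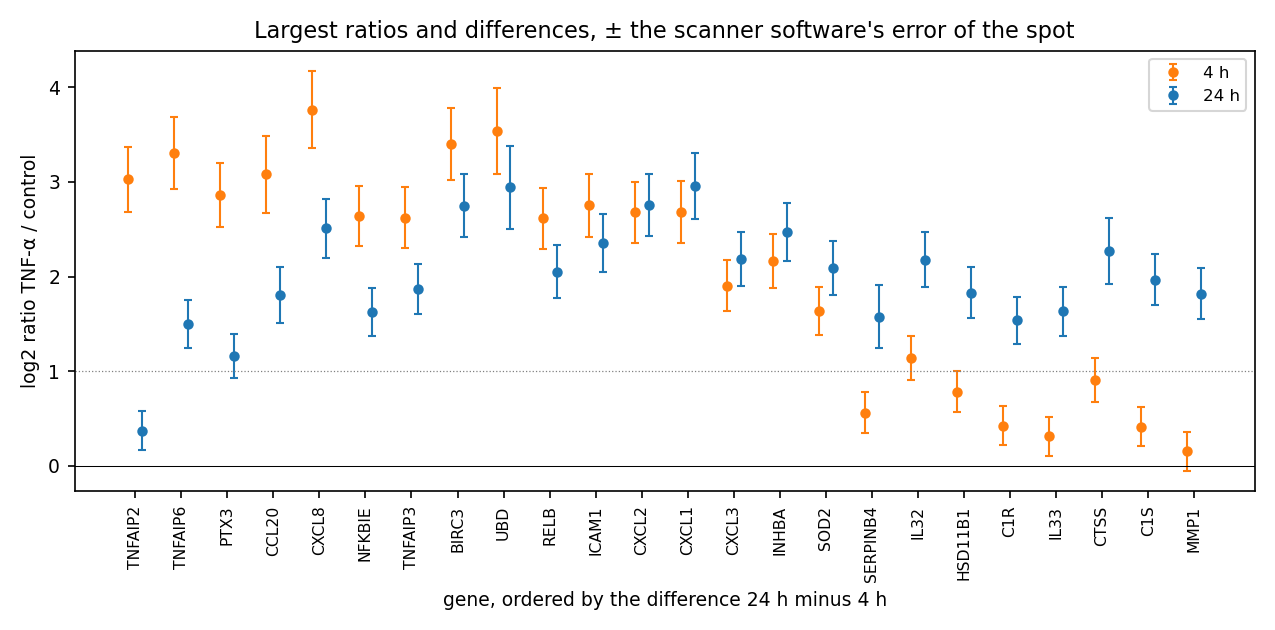
Log2 ratio of TNF-α over control (vertical axis) at 4 h (orange) and 24 h (blue) for 24 named genes measured in both channels of both arrays, ordered along the horizontal axis by the difference 24 h minus 4 h. Points are 1 array each, bars the scanner software's error of the spot, and the dotted line 2-fold; TNFAIP2 is at 3.03 and 0.37, MMP1 at 0.15 and 1.82.

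The second comparison asked what differed after 24 h of TNF-α. The chemokine genes CXCL1 and CXCL2, with UBD and BIRC3, had the largest measured ratios among genes with a symbol in the values used here. CXCL1 was 7.76-fold higher (log2 ratio 2.96 ± 0.35), UBD 7.70-fold (2.94 ± 0.44), CXCL2 6.75-fold (2.75 ± 0.33), BIRC3 6.72-fold (2.75 ± 0.33), CXCL8 5.70-fold (2.51 ± 0.31) and INHBA 5.54-fold (2.47 ± 0.31). ICAM1 stood at 5.10-fold (2.35 ± 0.31) and CTSS, which encodes the lysosomal protease cathepsin S, at 4.81-fold (2.27 ± 0.35). With the software's processed signals this order changed, to log2 ratios of 4.09 for UBD, 3.01 for CTSS, 2.99 for CXCL1, 2.81 for BIRC3 and 2.74 for CXCL2. In all, 118 measured genes were at least 2-fold higher and 3 at least 2-fold lower in the values used here. Of the called genes 31 had other probes, and in 9 of these all probes passed 2-fold the same way. With the lower bounds given next, 94 of the higher calls had a RefSeq symbol. The lower bounds added 7 higher genes, SERPINB2 (4.19-fold), CSF3 (3.51-fold), COXFA4L3 (2.94-fold), CFB, a complement factor (2.64-fold), CSF2 (2.34-fold), TNIP3 (2.25-fold) and CCL5 (2.13-fold), the last named after its value was seen. Each of these bounds equals the probe's own ratio. Those of CSF2, TNIP3 and CCL5 exceeded 2-fold by less than the software's error of the spot. A transcript without a symbol, whose probe lies close to that of SERPINB2 by the coordinates in the scanner output, was 8.00-fold higher (3.00 ± 0.36), the largest measured ratio at 24 h, described here after its value was seen.

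Chemokines had 6 of 12 measured members past 2-fold at 24 h (median 0.64, percentile 100.0), among them CXCL3 at 4.55-fold (2.19 ± 0.29), CCL20 at 3.49-fold (1.80 ± 0.30) and CCL2 at 2.14-fold (log2 error 0.29). Cytokines had 6 of 17 (median 0.41, percentile 100.0), with IL32 at 4.53-fold (2.18 ± 0.30), IL6 at 3.88-fold (1.96 ± 0.30), IL1B at 3.84-fold (1.94 ± 0.27) and IL1A at 3.45-fold (1.79 ± 0.28). Of NF-κB regulators, 6 of 24 were past 2-fold (median 0.47, percentile 100.0), including RELB at 4.14-fold (2.05 ± 0.28), TNFAIP3 at 3.65-fold (1.87 ± 0.27), NFKBIE at 3.08-fold (1.62 ± 0.25) and NFKBIA at 3.01-fold (1.59 ± 0.25). Survival genes had 3 of 18 (median 0.21, percentile 99.95), SOD2 being 4.26-fold higher (2.09 ± 0.28), or 1.28 in log2 as the mean over its probes. Among 14 measured adhesion molecules ICAM1 was again the only gene past 2-fold (median 0.17, percentile 99.68). SELE and VCAM1 were not well above background in either channel at 24 h.

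Antigen presentation by MHC class I had 3 of 20 members past 2-fold (median 0.40, percentile 100.0). TAP1 was 2.54-fold higher (1.35 ± 0.24), TAPBP, which encodes tapasin, also 2.54-fold (1.34 ± 0.24) and the immunoproteasome subunit gene PSMB8 2.07-fold (1.05 ± 0.23), with PSME2 at 0.99 ± 0.22. As the mean over its probes TAPBP was at 0.59, short of 2-fold. For interferon-stimulated genes, 1 of 39 passed, RIGI at 3.61-fold (1.85 ± 0.28), and the median was 0.23 (percentile 100.0). Matrix genes had 2 of 34 (median 0.24, percentile 100.0): CTSS, and the interstitial collagenase gene MMP1 at 3.53-fold (1.82 ± 0.27). Growth factors had 2 of 29 (median 0.18, percentile 100.0), INHBA and EREG, the latter at 2.22-fold (1.15 ± 0.23) and short of 2-fold as the mean over its probes (0.96).

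Oxidative and metal stress genes had 5 of 27 past 2-fold (median 0.19, percentile 99.26), but FTH1, MT1H, MT2A and, named after its value was seen, MT1X are among the brightest genes. With a loess span of 0.02 their log2 ratios were 0.36, 0.40, 0.33 and 0.37, against 1.20, 1.06, 1.14 and 1.02, and SOD2 alone stayed past 2-fold. That span would also remove a rise shared by the brightest genes. In the values used here the probes of FTH1 lay between 0.57 and 1.28, those of MT1H at 0.56 and 1.06, and those of MT2A at 0.96 and 1.14. ANXA2, past 2-fold at both times in the coagulation list, was at 0.61 and 0.64 with that span. In that list, 17 genes were measured at 24 h (median 0.06), with values of 0.71 for TFPI2 and 0.66 for PLAT. SLC7A2 was 2.18-fold higher (1.13 ± 0.25) and ASS1, of arginine synthesis, had a log2 ratio of 0.98 among 11 metabolic genes (median 0.09). CLDN1 was 2.96-fold higher (1.56 ± 0.25), the only gene of 16 in the junction list past the rule (median 0.13, percentile 98.51). ABCA1, the cholesterol exporter, was 2.41-fold higher (1.27 ± 0.25), but at 0.81 as the mean over its probes, in a cholesterol list of 28 genes with a median of -0.02, which was 0.30 under median centring.

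No member passed 2-fold at 24 h among pro-apoptotic genes and death receptors (21 genes, median 0.26, percentile 100.0), immediate-early genes (20 genes, 0.08), endothelial identity genes (25 genes, 0.10, percentile 98.08), cell cycle genes (42 genes, -0.10, percentile 0.62), the unfolded protein response (19 genes, 0.03) and glycolysis and hypoxia (24 genes, 0.09). Centring on the median without loess turned the cell cycle value to 0.21. Reference genes (20 genes, 0.16) and markers of leukocytes (11 genes, 0.26, percentile 99.98), fibroblasts and mural cells (13 genes, 0.08) and epithelial cells (9 genes, -0.11, percentile 1.71, but 3.33 among unmatched lists) had none either. Of the epithelial list, KRT8 was at -0.79 ± 0.22, KRT18 at -0.44 and MUC1 at 0.88. Its negative median turned to 0.11 under median centring. The reference gene medians were -0.01 at 4 h and -0.03 at 24 h with a loess span of 0.02. ACTB, EEF1A1 and RPL13A of that list are among the brightest genes.

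At 24 h the 3 genes past 2-fold lower were PNMT (-1.07 ± 0.23), which encodes the enzyme that makes adrenaline, and 2 probes without a gene symbol at -1.11 and -1.17, described here after their values were seen. The imprinted transcript H19 (-0.98 ± 0.23), HIRA (-0.98 ± 0.22), STAC2 (-0.96 ± 0.23), AKR1B10 (-0.96 ± 0.24), HPD (-0.85), OTULINL (-0.84) and GMPR (-0.84) came next, short of 2-fold. With the processed signals AKR1B10 (-1.19), H19 (-1.16), HPD (-1.08), GMPR (-1.06) and STAC2 (-1.04) passed it, and 18 genes were lower in place of 3. Bounds were 1.46-fold lower for BMP4, 1.45-fold for VIPR1, 1.42-fold for HOGA1 and 1.35-fold for OGDHL.

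**Figure D2:**
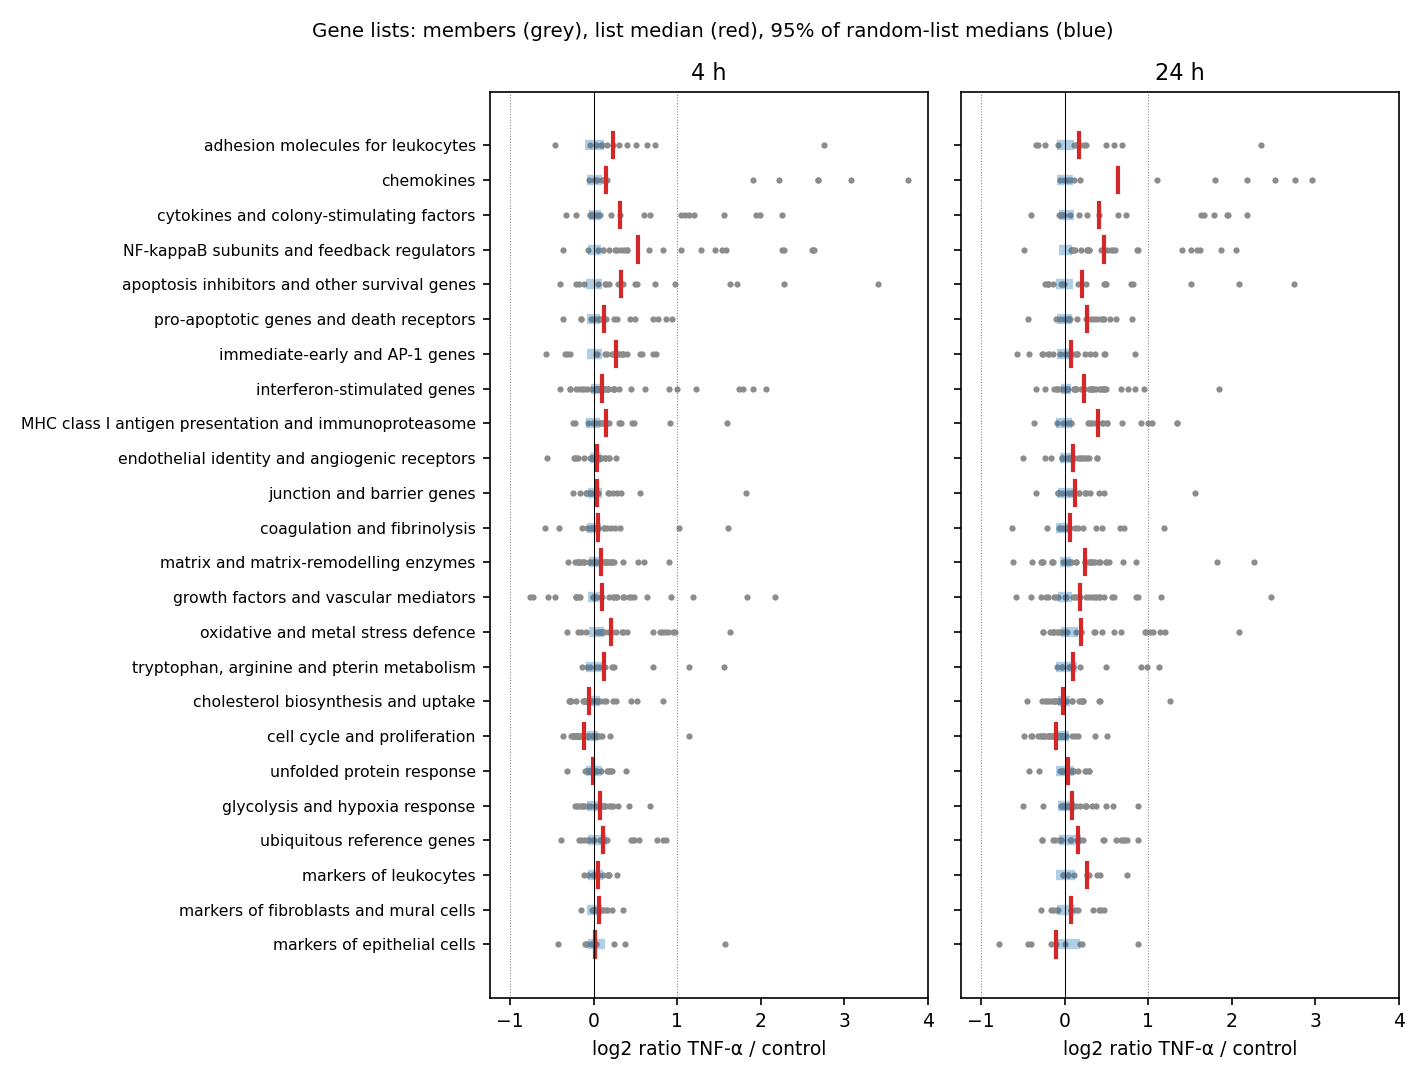
Log2 ratio of TNF-α over control (horizontal axis, 1 array per panel) for the measured members (grey dots) of 24 gene lists at 4 h and 24 h. Red bars are list medians, the blue band holds 95% of the medians of matched random lists, and dotted lines mark 2-fold; the NF-κB median is 0.53 at 4 h and 0.47 at 24 h, outside the band.

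The third comparison set the time points against each other, in 20106 genes measured in both channels of both arrays. Many transcripts were higher at both times, a group had smaller ratios at 24 h than at 4 h, and a smaller group had larger ones. Of 121 genes at least 2-fold higher at 4 h and 118 at 24 h in this set, 66 were in both, where independent lists would share 0.7; 9 of the 66 were among the brightest genes. No gene was 2-fold higher at one time and 2-fold lower at the other. Across genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.72 and a Spearman rho of 0.64, to which a dye effect shared by the arrays would add.

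The ratio was at least 2-fold smaller at 24 h for 20 genes, 15 of them at least 2-fold higher at 4 h. TNFAIP2 had the largest difference, from 8.16-fold to 1.29-fold (difference in log2 ratio -2.66 ± 0.40). It was followed by TNFAIP6 (-1.81 ± 0.46), PTX3 (-1.70 ± 0.41), the ion cotransporter gene SLC12A7 (-1.50 ± 0.35), CCL20 (-1.28 ± 0.50), EFNA1 (-1.26 ± 0.34), CXCL8 (-1.25 ± 0.52) and the transcription factor gene STAT5A (-1.20 ± 0.38). CCL2 differed by -1.12 ± 0.46. For TNFAIP2 the log2 control signal was higher at 24 h (14.58 against 13.86 at 4 h) and the TNF-α signal lower (14.95 against 16.89). SLC12A7 was short of 2-fold at 4 h as the mean over its probes (0.90). The other probe of STAT5A was at 0.86 at 4 h and 0.33 at 24 h. With the mean over probes, 16 genes had a ratio at least 2-fold smaller at 24 h, in place of 20. NF-κB regulators had a median difference of -0.17 (percentile 0.00 of random lists), survival genes -0.14 (0.00), immediate-early genes -0.10 (0.16) and adhesion molecules -0.12 (0.46). The guanylate-binding proteins GBP1 and GBP3 differed by -0.90 and -1.04.

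In the other direction, 8 genes had a ratio at least 2-fold larger at 24 h, and all 8 were at least 2-fold higher at that time. MMP1 went from 1.11-fold to 3.53-fold (1.67 ± 0.34). The complement proteases C1S and C1R differed by 1.56 ± 0.34 and 1.12 ± 0.32, CTSS by 1.36 ± 0.42, the alarmin gene IL33 by 1.32 ± 0.33, HSD11B1, which regenerates cortisol, by 1.05 ± 0.34, IL32 by 1.04 ± 0.38 and the serpin gene SERPINB4 by 1.02 ± 0.40. For SERPINB4 the log2 control signal was lower at 24 h (7.03 against 8.20 at 4 h) and the TNF-α signal no higher (8.61 against 8.76), and for C1R the control signal was lower too (9.89 against 10.56). The control signal of C1S was also lower (10.84 against 11.36), with a higher TNF-α signal (12.80 against 11.77). MHC class I genes had a median difference of 0.22 (percentile 100.0), matrix genes 0.17 (100.0), glycolysis and hypoxia genes 0.09 (99.09) and interferon-stimulated genes 0.08 (99.77). Spike-in centring would lower every difference alike, by 0.14, which is more than the last 2 of these medians. The 11 chemokine genes measured at both times had a median difference of 0.03 (percentile 71.12) and a mean of -0.27, with 3 at least 2-fold smaller at 24 h and 0 larger. CXCL1, CXCL2 and CXCL3 differed by 0.27, 0.07 and 0.28, less than the software's error of each difference, and IL1B by 0.00. Counts of such differences moved with the processing: the software's processed signals gave 51 and 27 genes in place of 20 and 8.

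**Figure D3:**
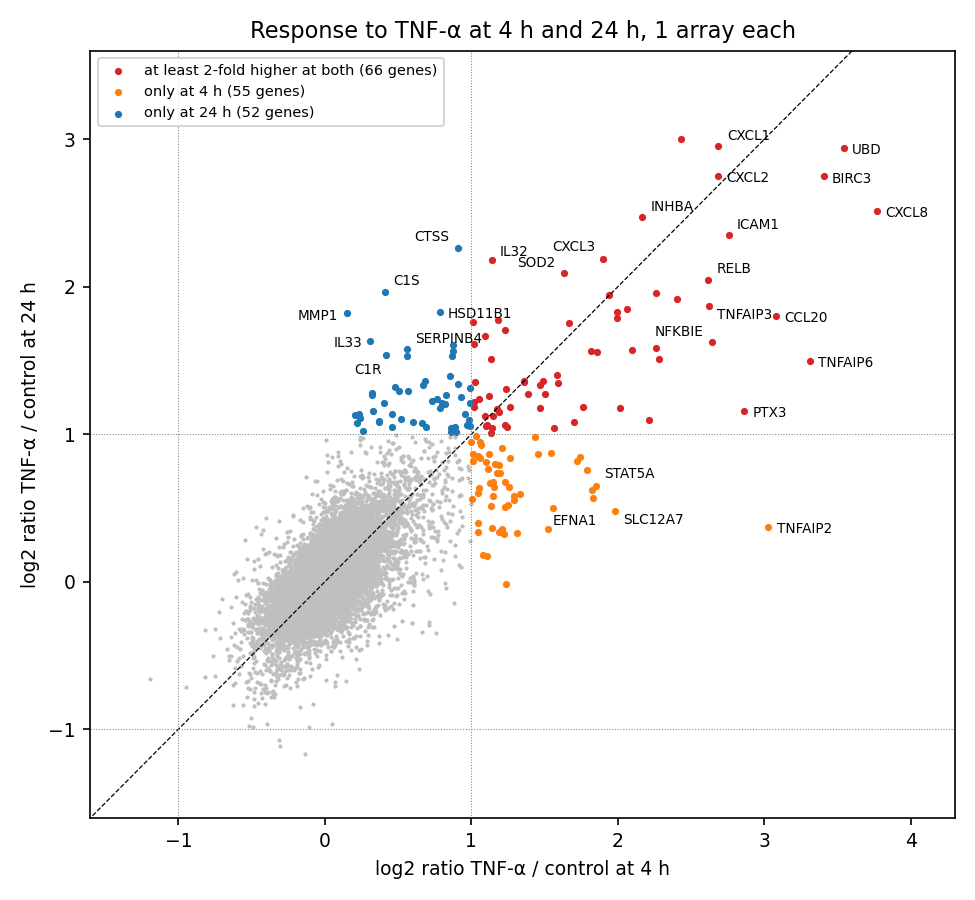
Log2 ratio of TNF-α over control at 4 h (horizontal axis) against 24 h (vertical axis) for 20106 genes, 1 array each, with the dashed line at equal ratios and dotted lines at 2-fold. Coloured points are genes at least 2-fold higher at both times (66, red), at 4 h only (55, orange) or at 24 h only (52, blue); few points lie below the dotted lines at -1.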

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

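Tests on the brightest genes were chosen after the result was seen; the tests on other probes of the same genes were set before. The comparisons did not use the spike-in controls. Their offset of the log2 ratio, taken as the intercept of a line of observed on expected values, was -0.677 at 4 h and -0.535 at 24 h, where 0 was expected. The slopes were 0.859 and 0.866, so the shortfall differed between controls of different expected ratio. The median SD between spots was 0.051 and 0.039. The amounts of spike-in mix added to each channel are not given in the sources used here, so unequal amounts are not excluded.

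The first pattern weighed was the group of 66 genes at least 2-fold higher on both arrays, since an effect of the dye on a probe would repeat on both. Such an effect belongs to the probe, so other probes of the same genes should lie near 0. The 31 other probes of 20 of these genes had a median log2 ratio over both arrays of 0.874 (quartiles 0.18 and 1.244), against 1.355 for the probes that made the calls, and 27 of the 31 had the same sign. This argues against a dye effect of the probe as the whole explanation for those genes as a set. It leaves such an effect open for genes with 1 probe and for the bright genes weighed next. No gene was at least 2-fold lower on both arrays, so the corresponding test had 0 probes to run on.

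The second pattern was the set of 9 bright genes within that group, RPL14, RPL23, RPL35, RPS2, RPS14, ANXA2 and 3 without a symbol. A candidate explanation is a dye trend at the brightest spots that the loess left in place, in which case dimmer probes of the same genes should lie near 0. The 7 probes of 5 of these genes with a mean log2 signal under 16 had a median log2 ratio over both arrays of 0.035 (quartiles -0.021 and 0.133), against 1.108 for the probes that made the calls. A rise particular to ribosomal protein transcripts would set them apart from others of the same brightness, but the 82 measured ribosomal protein genes exceeded their 20 neighbours in brightness by a median of only 0.064 at 4 h (SD 0.249) and 0.029 at 24 h (SD 0.241). These calls may thus be technical, although an effect of the dye on single probes and dimmer probes that read other transcripts stay open, and 4 of the 9 genes had no dimmer probe to compare.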

How the results depend on the processing

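The 3 settings added after the data were seen are the spike-in centring, the loess span of 0.02 and leaving out genes with a mean log2 signal of 16 or more. No paired analysis was possible because each time point is 1 array and no test was run. With 1 array per group no array could be left out, and dim spots limit the rest: their ratios are pulled toward 0 and depend on the background correction. Where not stated, the cause of a shift was not tested.

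The counts of higher genes, 136 at 4 h and 125 at 24 h with the lower bounds, were 111 and 104 with the mean over a gene's probes. They stayed within 1.5 times under every setting that kept the 2-fold rule except median centring without loess (500 and 549, with 0 and 1 lower) and spike-in centring of measured genes (1269 and 761, with 0 and 0 lower). The first leaves the trend of the ratio with brightness in place, so that the median of measured genes lay at 0.148 and 0.157, and the second moves every ratio by the offset of the controls. Requiring 3-fold gave 45 and 36 higher and 0 and 0 lower, and 1.5-fold gave 414 and 453 higher and 32 and 103 lower, by construction. The counts of lower genes, 1 and 3, became 13 and 18 with the software's processed signals and again 13 and 18 with the deposited table, 3 and 5 with an offset of 16, and 5 at 24 h with no background correction. Of the higher calls, 121 and 101 also passed 2-fold in the processed signals, where 92.9% and 88.5% of calls were higher, against 99.3% and 97.7% in the values used here.

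Genes with a larger or smaller ratio at 24 h, 8 and 20, became 27 and 51 with the processed signals and with the deposited table, 91 and 118 at 1.5-fold, 1 and 3 at 3-fold, and 4 and 33 with spike-in centring. The correlation of the time points, 0.723, was 0.846 with median centring, 0.672 with the processed signals and with the deposited table, 0.66 without a filter on dim probes, 0.712 with the mean over probes, 0.702 with an offset of 16, 0.695 with the span of 0.02 and 0.702 without bright genes.

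Median centring reversed 3 list medians that lay outside the central 95% of random lists: cell cycle at 4 h (0.248) and 24 h (0.211) and epithelial markers at 24 h (0.112). It moved another 25 of 48 list medians by more than the software's median error, and the processed signals moved 1. Of 250 ratios of named genes, all 250 kept within the software's error with no background correction or with scaling between arrays. This held for 241 with an offset of 16, 234 with the span of 0.02, 218 with the mean over probes, 203 with the processed signals, 137 with median centring and 0 with spike-in centring, which shifts every ratio of an array alike. Unmatched random lists moved 4 of 72 percentiles across the edge of the central 95%: epithelial markers at 24 h came inside (3.33), and cholesterol genes at 4 h (2.13) and reference genes at 4 h (98.51) and 24 h (99.95) fell outside.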

Other observations

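The test on the SD of all ratios was chosen after the result was seen; those on interferon genes and scale normalisation were set before the data were examined. The control channels, set against each other after normalisation between the arrays, show how untreated cells differed between 4 h and 24 h, although array and time cannot be separated there. Of 20308 genes, 37 were at least 2-fold higher at 24 h and 28 at least 2-fold lower. Cholesterol synthesis genes were higher at 24 h, with a median difference of 0.26 in log2 signal over 28 genes (percentile 100.0 of matched random lists), as were glycolysis and hypoxia genes (0.11, percentile 99.85) and cell cycle genes (0.10, percentile 99.89), with 0 members of the 3 lists at least 2-fold higher. Growth factors and vascular mediators were lower at 24 h (-0.09, percentile 1.01), with 3 genes at least 2-fold lower, as were oxidative and metal stress genes (-0.10, percentile 1.34), with 2. Among genes lower at 24 h, chosen after their values were seen, was ANKRD1 (-1.42), a gene that responds to stretch and to YAP. The keratin genes KRT14 (-1.33), KRT17 (-1.31), KRT6C (-1.29) and KRT16 (-1.25), chosen in the same way, were lower too. Several of the genes furthest up, such as PYDC1 (1.83) and ZNF792 (1.75), had ratios of TNF-α over control near 0 on both arrays, so both channels of the 24 h array were brighter at those spots. In the same way both channels were dimmer at 24 h for KRT14 (ratios of 0.02 and 0.18), KRT17 (-0.06 and 0.05) and KRT16 (-0.12 and 0.02). The ratios of KRT6C were 0.02 and 0.81. Ratios near 0 cannot tell a change with time from a difference between the arrays.

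Some classical endothelial targets and markers were not seen above background. SELE, VCAM1 and PECAM1 were not well above background in any of the 4 channels, TNF-α channels included, while ICAM1 was 6.75-fold and 5.10-fold higher. Other genes of endothelium, such as TEK, ENG, ERG and SOX17, chosen after their signals were seen, were well above background in all 4 channels. Keratin genes KRT8 and KRT18 were as well, and so were DCN, LUM and FAP of the fibroblast and mural cell list. Log2 control signals at 4 h were 15.68 for KRT8, 16.05 for KRT18, 15.66 for DCN, 11.10 for LUM and 11.75 for FAP. Those of the endothelial genes SOX17, SOX18, GATA2 and FLI1 were 12.74, 12.07, 9.45 and 7.82. Signals of different probes are not compared as amounts here. KRT14 and KRT17 had log2 control signals of 11.03 and 12.02 at 4 h. At 4 h, 26 of 38 genes of the endothelial identity list were measured. The same held for 12 of 14 epithelial markers, 15 of 18 of fibroblasts and mural cells, and 13 of 18 of leukocytes. No explanation was tested for this pattern of markers.

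Interferon-stimulated genes made the third pattern weighed: their median difference between 24 h and 4 h was 0.081 (39 genes, percentile 99.77) and their mean 0.028, while GBP1, GBP3 and IRF1 had smaller ratios at 24 h. Members past 2-fold numbered 6 at 4 h and 1 at 24 h, and GBP2, at 1.91 at 4 h, was left out of the 39 with its control channel not well above background at 24 h. A hypothesis set in advance was that an interferon gene is switched on by 4 h: of 16 on the array, 5 were well above background at 4 h and 0 of them was at least 2-fold higher, but the others, IFNB1 and IFNG among them, were not well above background, so the bound set in advance asked for too few measured genes and the hypothesis stays open. Scale normalisation between the arrays moved the median only to 0.077 (percentile 99.6) and so decides nothing about a difference in scale, but the SD of all log2 ratios at 24 h was 1.022 times that at 4 h, where stretching would need a factor of 2.226 between the list's medians. The cause of the shift stays open.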
